A study of Mus musculus with 4 samples.

How the data were processed

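The series holds 4 mouse libraries, 1 per group: CTCF in Rag2-/- pro-B cells, in wild-type mature B cells and in wild-type DP T cells, and Rad21 in Rag2-/- pro-B cells. Groups were taken from the labels. The measurement is chromatin immunoprecipitation followed by paired-end sequencing of 76-nt reads, per the labels' protocols, with insert sizes given as 332, 307, 348 and 159 nt for pro-B, mature B, DP T and Rad21. Reads were aligned with Bowtie 0.12.2, per the submitters' processing notes, which name mm8.

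The deposited peak lists give 1 score per peak, made by the authors with MACS per the file headers. The lowest score was 50 in each of the 4 lists. The definition of the score, the MACS version, any control library and the handling of duplicates are not given in the sources used here, and the score was used for ranking and for a stricter threshold of 100. The value 3100.0 recurred in 426 pro-B, 760 mature B and 169 Rad21 peaks, as a ceiling would, so the order among peaks at that score is not resolved, although the highest score in each of these 3 lists was 3233.06. Median scores were 288, 356, 188 and 216 in the pro-B, mature B, DP T and Rad21 lists. The deposited alignments give 1 line per read, with position and strand. Column 4 takes 3 values (0, 1 and 2) whose meaning is not given in the sources used here. It was used in the closing section, and in the report to say which named sites and regions lie where it differs.

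Peaks and alignments were checked against each other before they were joined. In 299 of 327 windows of 8 Mb a clear best shift between reads and peaks was found. It exceeded 1 kb in 277 of these windows (92.6%), with a median of 84.4 kb, a maximum of 1.43 Mb and 167 different shifts. Reads on chromosome 7 reached position 152524499 and peaks 145108955. The 2 kinds of file therefore lie on different assemblies, and no conversion between them was made. Peak overlaps were computed in mm8. Read counts were made on the alignments' own coordinates, whose build is not given in the sources used here.

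This led to departures from the plan, which had read counts at the merged peaks of the authors. Sites were called from the reads instead, in windows of 300 bp in steps of 50 bp against the larger of the genome-wide and the local background of 10 kb, at a Poisson probability of 1e-07, on end counts divided by 2 because each fragment has 2 ends. Sites overlapping between the 3 CTCF libraries were merged, giving 42538 sites, 41363 of them on autosomes. The planned grouping of sites by gene lists and receptor loci was left out because no annotation of either assembly was at hand. Ties in peak score could not be broken by reads for the same reason.

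Reads were reduced to distinct ends, 1 per position and strand, and shifted towards the fragment centre by 0.5 of the fragment length found by strand cross-correlation on chromosome 19 (335, 295, 335 and 152 bp for pro-B, mature B, DP T and Rad21). Ends within 300 bp of the site centre were counted. Counts of a pair of libraries were scaled so that the median log2 ratio over sites called in all 3 CTCF libraries was 0, and the log2 ratio was taken with a pseudocount of 1. Sites needed at least 50 ends in the higher library, which on unscaled counts favours the deeper library. Intervals of ratios are exact conditional binomial 95% intervals on halved end counts, and intervals of shares are Clopper-Pearson 95% intervals. A ratio against 0 ends is given as the lower limit of its interval. Equal depth means equal numbers of distinct ends after thinning, and the share of ends at CTCF sites was not made equal. Equal-depth ratios used the sites called from the unthinned reads, also where sites were restricted to those called in 1 library. For these ratios the counts were thinned and the minimum of 50 ends was lowered too. It was multiplied by the ratio of DP T to pro-B distinct ends (6543135 to 14605625). The lower minimum also held for the DP T library, which was not thinned.

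Peaks shared between lists overlapped by at least 1 bp. Random overlap was taken from 100 placements on the same chromosome. Peaks per 2-Mb stretch of autosomes were compared in steps of 500 kb. Rad21 at sites was counted in the same 600-bp windows, as a fold over the genome mean. Classes were also compared with sites of all 3 cell types matched on the CTCF count. For coverage, ends outside called sites (1 kb each side) were counted in 50-kb bins with at least 50 ends in the reference, scaled to the median bin. Regions are runs of at least 2 adjacent bins with a ratio of at most 0.7.

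The items named were fixed by rule: for each CTCF pair the 12 autosomal sites with the largest and the 12 with the smallest log2 ratio, the 12 strongest Rad21 peaks without a CTCF peak of any list within 1 kb, the 12 strongest pro-B CTCF peaks without a Rad21 peak within 1 kb, and up to 12 coverage regions per library by length. These rules, the thresholds above other than the calling rule and the minimum per bin, and all alternatives not listed next were chosen before the data were examined. The calling rule, the minimum of ends per coverage bin, the strongest peaks private to 1 list, the groups of peaks by strength, the ranking of 2-Mb stretches and the equal list lengths in the chromosome 12 stretch, the equal-depth ratios, the restriction to sites called in the second library of a pair, and the direct comparison of coverage between mature B and DP T cells were added afterwards.

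The alternatives were a stricter score, other definitions of overlap, equal list lengths, no sex chromosomes, all reads counted, other windows, scalings, pseudocounts and count minimums, background subtraction, unshifted reads, other bins and ratio limits, and Rad21 as the reference for coverage. The counting was tested on simulated reads on chromosome 19 at the depths of the pro-B and DP T libraries, with 1157 sites of which 200 were changed. In the simulated deeper library no called window lay outside the simulated sites. Its background was drawn evenly along the chromosome, so false calls on uneven real background were not tested. A true 4-fold rise gave a median log2 ratio of 1.55 against 1.97 expected, with the expected ratio inside the interval at 68.0% of these sites, and a true 2-fold rise gave 0.88 against 0.98. Of unchanged sites 2.11% passed 2-fold in the direction of the deeper library and 0% in the other. Of 50 sites each, 30 of those lowered 2-fold and 19 of those lowered 4-fold reached the count minimum, against all 50 of those raised 2-fold or 4-fold. All 19 simulated segments of low coverage, each 8 bins long, were found, with 16 other low runs of at most 3 bins. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.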

Results

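CTCF, the zinc finger protein that binds insulators and loop anchors, was mapped by chromatin immunoprecipitation and sequencing in mouse pro-B cells lacking Rag2, in wild-type mature B cells and in wild-type double-positive (DP) T cells. Rad21, a subunit of the cohesin ring, was mapped in Rag2-/- pro-B cells. Rag2 is one of the proteins that cut DNA when antigen receptor genes are rearranged, so the pro-B cells cannot rearrange these genes. There was 1 library per group and therefore no replicate. No difference below has a replicate check or a p-value, and every interval covers counting error only. On simulated reads the intervals of ratios held the expected value at 96.4% of unchanged sites, 68.0% of sites raised 4-fold, where the ratio was underestimated, and 100.0% of sites lowered 4-fold. Cell stage and Rag2 genotype changed together between the pro-B cells and both other cell types. The labels of the series place the immunoglobulin heavy chain locus at the centre of the study.

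The alignment files held 24940054 reads for CTCF in pro-B cells, 24222912 in mature B cells, 20669066 in DP T cells and 28665642 for Rad21. The share of reads with a distinct end differed widely: 58.6% in pro-B, 61.5% in mature B, 31.7% in DP T and 86.0% in the Rad21 library. The DP T library thus held 6543135 distinct ends, against 14605625 in pro-B, 14907926 in mature B and 24642842 for Rad21. Of these distinct ends 28.3%, 24.2% and 20.8% lay at called CTCF sites in pro-B, mature B and DP T cells. The deposited peaks are in mm8 coordinates, whereas the deposited alignments did not match the peaks position by position, so peak positions below are mm8 and read positions are those of the alignment files, whose build is not given in the sources used here.

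The number of CTCF peaks fell from pro-B cells to mature B cells to DP T cells. The authors' lists held 49718 peaks in pro-B, 35706 in mature B and 29053 in DP T cells. The order was the same among windows called by 1 rule after every library had been thinned to the DP T depth, where 28271, 20885 and 17522 sites were called. Without thinning, the same rule called 40855, 28427 and 17522 sites. Thinning did not equalise the share of ends at CTCF sites, which fell in the same order (28.3%, 24.2% and 20.8%). With 1 library each, a difference in library quality cannot be told apart from one between cell types.

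Most peaks of the shorter lists were also peaks in pro-B cells. Of the mature B peaks 90.3% overlapped a pro-B peak by at least 1 bp (95% Clopper-Pearson interval 90.0 to 90.6), and of the DP T peaks 89.3% did (89.0 to 89.7). DP T peaks overlapped mature B peaks in 85.2% of cases (84.8 to 85.6). In the other direction 65.6% of the pro-B peaks overlapped a mature B peak (65.2 to 66.0), 51.7% a DP T peak (51.2 to 52.1) and 48.2% a peak in both (47.8 to 48.7). Peaks placed at random on the same chromosome overlapped the other list in a median of 3.52% to 6.48% of cases over 100 draws. The directions differed less between lists of equal length: among the 29053 strongest peaks of each list, 83.7% of pro-B peaks were in mature B cells and 77.6% in DP T cells, against 82.9% and 79.0% in the other direction.

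Merged into 54630 sites, the lists placed 23287 sites in all 3 cell types, 8317 in both B lineage stages but not DP T cells, 15392 in pro-B cells alone, 2972 in mature B cells alone and 2567 in DP T cells alone. Peaks found in 1 list alone were weak as a class, with median authors' scores of 91.75, 67.48 and 59.43 in pro-B, mature B and DP T cells, against 804, 788 and 257 for sites in all 3. Some were strong. The strongest peak of the pro-B list without a counterpart lay on chromosome 3 from 129248182 to 129251660 (score 3100.0, a value shared by 426 peaks of that list, so it does not rank them) and overlapped a Rad21 peak. On chromosome 14 the peak from 78949406 to 78951229 scored 1816, again with Rad21. In mature B cells the strongest private peak was on chromosome 12 from 113704769 to 113706186 (score 1051), with no Rad21 peak in pro-B cells. In DP T cells it was on chromosome 9 from 35054297 to 35055498 (score 766), with a Rad21 peak. Of the 12 strongest private peaks in each list, 10 of the pro-B set, 5 of the mature B set and 3 of the DP T set overlapped a Rad21 peak of pro-B cells. The mature B and DP T sets lack a pro-B CTCF peak by selection, and Rad21 was measured in pro-B cells only. Fewer Rad21 overlaps in these sets than in the pro-B set are thus close to built in.

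**Figure D1:**
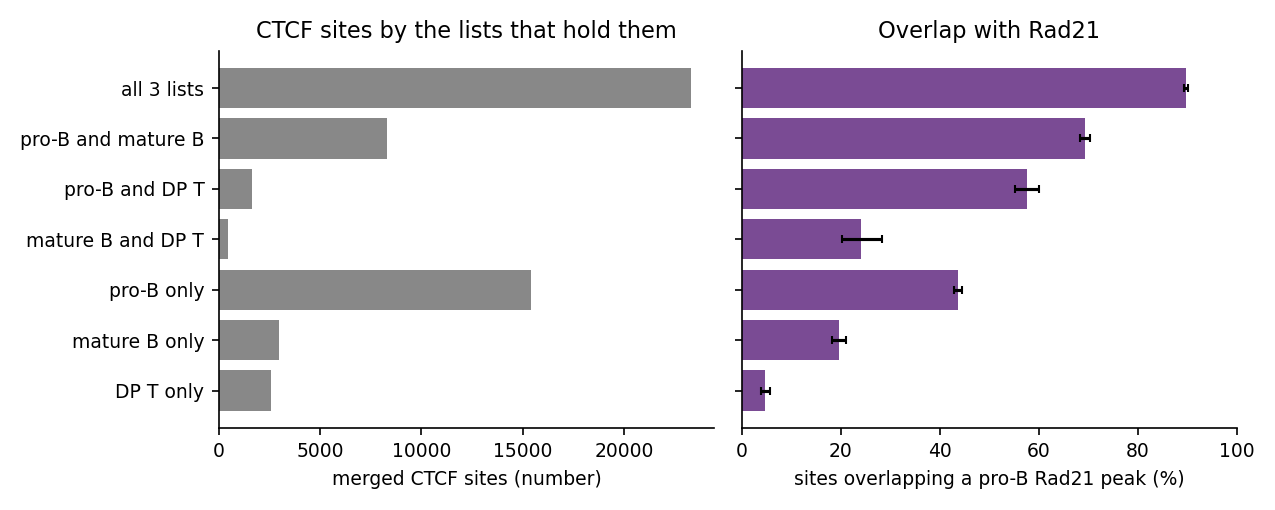
The left panel plots the number of merged CTCF sites (mm8) by the authors' lists that hold them, and the right panel plots the percentage of each class that overlaps a Rad21 peak of pro-B cells, with 95% Clopper-Pearson intervals as error bars. Sites in all 3 lists overlapped Rad21 in 89.8% of cases, sites in DP T cells alone in 4.75%. The latter lack a pro-B CTCF peak by definition.

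CTCF read density separated pro-B from mature B cells mostly through sites that were higher in pro-B cells. Of 30211 autosomal sites with at least 50 distinct ends in the higher library, 7663 were at least 2-fold higher in pro-B cells and 396 at least 2-fold higher in mature B cells. The SD of the log2 ratio over sites was 0.98. With both libraries thinned to the DP T depth, and the minimum of ends lowered in proportion, the split was 7604 to 585. The direction was kept among the sites called from the unthinned mature B reads. With counts at equal depth, 2893 of these were at least 2-fold higher in pro-B and 584 in mature B cells. The 12 sites with the highest ratio had 0 ends in mature B cells and 56 to 83 in pro-B cells, and 8 of them were also Rad21 sites. Among them, the chromosome 2 site from 118927201 to 118927800 lies where the fourth column of the alignments differs in both pro-B libraries. The site on chromosome 16 from 21768251 to 21768850 held 83 pro-B ends against 0, a ratio of at least 11.1 by its counting interval, with 118 Rad21 ends. On chromosome 12 the site from 117235101 to 117235700 held 60 pro-B ends, none in mature B and 6 in DP T cells, with 64 Rad21 ends.

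The sites most raised in mature B cells mostly lacked Rad21 in pro-B cells: of the 12 with the lowest ratio of pro-B to mature B, 1 was a Rad21 site. Of these 12 sites 0 were called for CTCF in pro-B cells, where Rad21 was measured, so little Rad21 there is close to built in. The site on chromosome 12 from 114495401 to 114496000 held 150 ends in mature B cells, 3 in pro-B cells and 6 in DP T cells. The ratio of pro-B to mature B cells there had a counting interval of 0.0003 to 0.0804. On chromosome 9 the site from 76212651 to 76213250 held 56 mature B ends, 2 pro-B ends and none in DP T cells, and on chromosome 15 the site from 102156301 to 102156900 held 78, 4 and 16. A site on chromosome 11 from 3953501 to 3954100 held 237 mature B ends, 81 DP T ends and 6 pro-B ends. It lies next to a stretch, from 3954751 to 3959000, without any read in either pro-B library. Sites on chromosome 2 from 120304201 to 120304800 and from 120962801 to 120963400, both among the 12, lie where the pro-B reads of both libraries differ from the wild-type reads in the fourth column of the alignments.

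Against DP T cells, 9196 of 29120 sites were at least 2-fold higher in pro-B cells and 434 at least 2-fold lower, with an SD of 1.01. With both libraries at equal depth the split was 9135 to 847, where depth is the number of distinct ends and the share of ends at CTCF sites still differed (28.3% and 20.8%). The minimum of ends was lowered with the depth. With counts at equal depth, sites called in pro-B cells split 9115 to 622 and sites called in DP T cells 806 to 796. The calls came from the unthinned reads, which are deeper in pro-B cells. Each restriction favours the library that called, and both were added after the data were examined. The 12 sites with the highest ratio had 0 DP T ends and 93 to 124 pro-B ends, and 10 were Rad21 sites. Among them, the chromosome 5 site from 15133951 to 15134550 lies where the fourth column of the alignments differs in both pro-B libraries. The site on chromosome 4 from 87005251 to 87005850 held 124 pro-B ends against 0, a ratio of at least 6.59 by its counting interval, and that on chromosome 1 from 146090501 to 146091100 held 107 pro-B and 93 mature B ends. Of the 12 sites highest in DP T cells, 6 were called in pro-B cells and 1 was a Rad21 site. That 1 was the chromosome 2 site from 120304201 to 120304800, where the fourth column of the alignments differs in both pro-B libraries. The site with the most extreme log2 ratio, taken with the pseudocount, was on chromosome 12 from 108324351 to 108324950, with 129 DP T ends, 34 mature B ends and 10 pro-B ends. This is a 31.9-fold ratio after scaling without the pseudocount, with a counting interval of the pro-B to DP T ratio of 0.0099 to 0.0775. By the ratio without the pseudocount the chromosome 11 site at 3953501 was further apart (33.4-fold). On chromosome 1 the site from 93497151 to 93497750 held 116 DP T, 35 pro-B and 11 mature B ends.

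Mature B and DP T cells are both wild type, so that pair leaves the Rag2 genotype out. Here 3779 of 21774 sites were at least 2-fold higher in mature B cells and 570 in DP T cells, with an SD of 0.83. With both libraries at equal depth the split was 3785 to 1640, and with all deposited reads counted it was 5946 to 2737. The equal-depth split also rests on a lower minimum of ends, and a minimum of 20 ends without thinning gave 6368 to 1783. The effect of depth is therefore not separated from that of the minimum. Each way of choosing sites favoured the library that called them. With counts at equal depth, sites called from the unthinned mature B reads split 3757 to 956, and sites called in DP T cells 726 to 1442. The 12 sites with the highest ratio had 0 DP T ends, and all 12 were called in pro-B cells too. The site on chromosome 1 from 109249501 to 109250100 held 137 mature B and 75 pro-B ends, and that on chromosome 17 from 66135501 to 66136100 held 126 and 101. Of the 12 sites highest in DP T cells, 11 were called in pro-B cells as well, among them chromosome 2 from 172650651 to 172651250, with 70 DP T, 44 pro-B and 9 mature B ends.

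**Figure D2:**
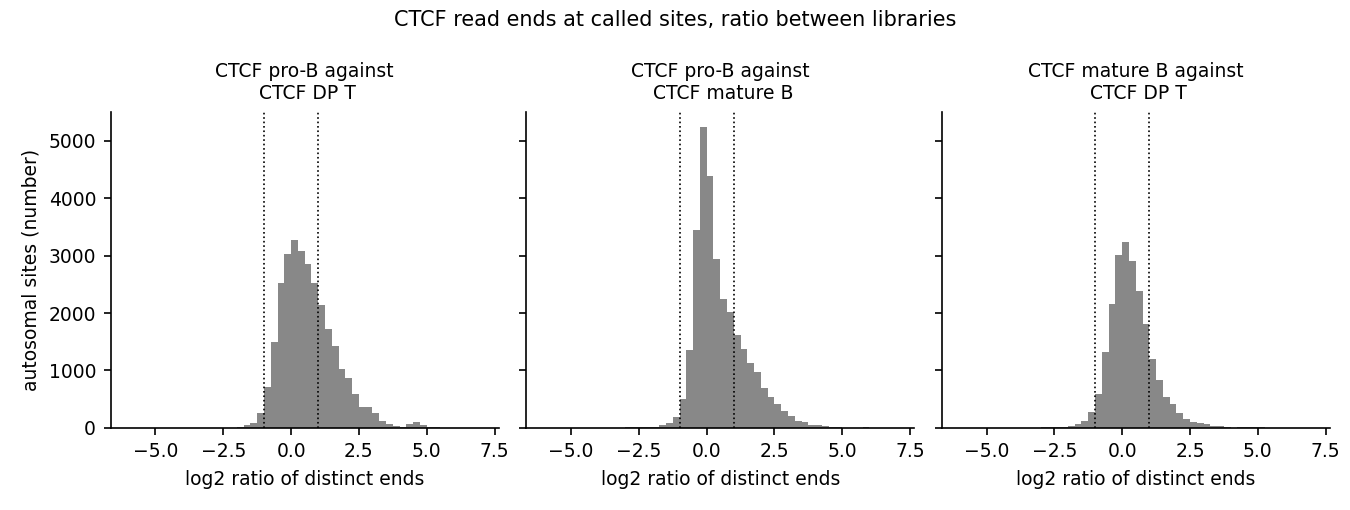
Each panel plots the number of autosomal sites (vertical axis) by the log2 ratio of scaled distinct read ends between 2 CTCF libraries (horizontal axis), for sites with at least 50 ends in the higher library, with dotted lines at a 2-fold difference. The right tail is longer than the left in each panel, with 9196, 7663 and 3779 sites past the right line.

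In pro-B cells cohesin lay mostly where CTCF lay. Of 45848 Rad21 peaks 81.0% overlapped a pro-B CTCF peak (80.7 to 81.4) and 83.1% a CTCF peak of any of the 3 cell types (82.8 to 83.5). Of the pro-B CTCF peaks 70.5% overlapped a Rad21 peak (70.1 to 71.0). Random placement gave 4.66% and 4.15%. The overlap rose with peak strength. Over 5 groups of equal size, from the weakest to the strongest by the authors' score, the share of CTCF peaks with Rad21 went from 30.8% to 53.5%, 77.2%, 93.1% and 98.1%, and the share of Rad21 peaks with CTCF from 44.3% to 71.7%, 90.8%, 98.6% and 99.8%. A reciprocal overlap of 50% lowered the shares to 34.6% of Rad21 and 31.9% of CTCF peaks. Rad21 peaks had a median width of 694 bp and CTCF peaks in pro-B cells of 1475 bp.

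Peaks of 1 protein alone were found in both directions. A total of 6807 Rad21 peaks (14.8%) had no CTCF peak of any list within 1 kb, with a median score of 66.1, and 1464 of them scored at least 100. The strongest were on chromosome 7 from 64028499 to 64029194 (score 964), on chromosome 11 from 105148601 to 105148929 (score 896) and on chromosome 6 from 68302775 to 68303566 (score 891). Conversely 13804 pro-B CTCF peaks (27.8%) had no Rad21 peak within 1 kb. The 12 strongest of these scored 2063 to 3100.0, and 12 were also peaks in DP T cells and 11 in mature B cells. They included chromosome 13 from 25022151 to 25023857 (score 3100.0), chromosome 14 from 54820182 to 54821766 (score 2865) and chromosome 8 from 74392813 to 74394507 (score 2683).

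Among CTCF sites called in 1 cell type alone, Rad21 in pro-B cells marked those of pro-B cells more often than those of mature B or DP T cells. Among autosomal sites called from the reads, a Rad21 call was present at 86.5% of sites bound in all 3 cell types, 39.1% of pro-B-only sites, 21.6% of mature B-only sites and 6.51% of DP T-only sites. The median Rad21 ends per 600 bp were 99, 27, 18 and 12, against a genome mean of 5.6. The difference between the shared and the pro-B-only sites shrank once sites were matched on the pro-B CTCF count, to 46.1% against 39.1%. With the same matching, shared sites had 61.9% against 53.2% of sites called in pro-B and DP T cells. They fell behind sites called in pro-B and mature B cells, with 63.3% against 68.7%. The mature B-only and DP T-only sites lack a CTCF call in pro-B cells, where Rad21 was measured, with medians of 22 and 20 pro-B CTCF ends, and no matching on the pro-B count was made for them.

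Distal chromosome 12 held many pro-B CTCF peaks that the mature B and DP T lists lacked. The 2-Mb stretch from 114500001 to 116500000 (mm8) held 107 CTCF peaks in pro-B, 54 in mature B and 37 in DP T cells, together with 141 Rad21 peaks in pro-B cells. It was picked, after the data were examined, as the stretch with the lowest ratio of DP T to pro-B peaks among 332 overlapping autosomal stretches of this length with at least 100 pro-B peaks. That ratio was 0.346, against a median of 0.654. The ratio of mature B to pro-B peaks was 0.505 against a median of 0.762, also the lowest of the 332, but it shares its denominator with the ratio used for the choice and is not independent of it. With at least 60 pro-B peaks, the stretch ranked 4 of 1138 for mature B and 2 for DP T cells. Among equally long lists the stretch held 61, 44 and 37 CTCF peaks, a smaller difference in the same order. Of its merged sites 49 were in pro-B cells alone, and 40 of those overlapped Rad21. A further 30 were in all 3 cell types, each with Rad21. Rad21 peaks were also more frequent than CTCF peaks there, with 1.32 for each pro-B CTCF peak against a median of 0.807, and 42 of the 141 did not overlap a pro-B CTCF peak. Read coverage between sites was also lower on distal chromosome 12, on the alignments' own coordinates. It was 0.462 of pro-B in mature B cells from 114700001 to 115200000 and 0.563 in DP T cells from 115250001 to 115450000. Reads and peaks lie on different assemblies, and the last read on chromosome 12 lay 830556 bp beyond the last peak. Whether these regions fall inside the stretch is therefore not known. Peak numbers were not corrected for coverage, so fewer peaks need not mean less CTCF binding. Antigen receptor loci were not placed on the files' coordinates, since no annotation of these builds was used here. The mouse RefSeq table used for names (GRCm38.p6) puts Igh on chromosome 12, Igk and Tcrb on chromosome 6, Igl on chromosome 16, Tcra and Tcrd on chromosome 14 and Tcrg on chromosome 13.

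**Figure D3:**
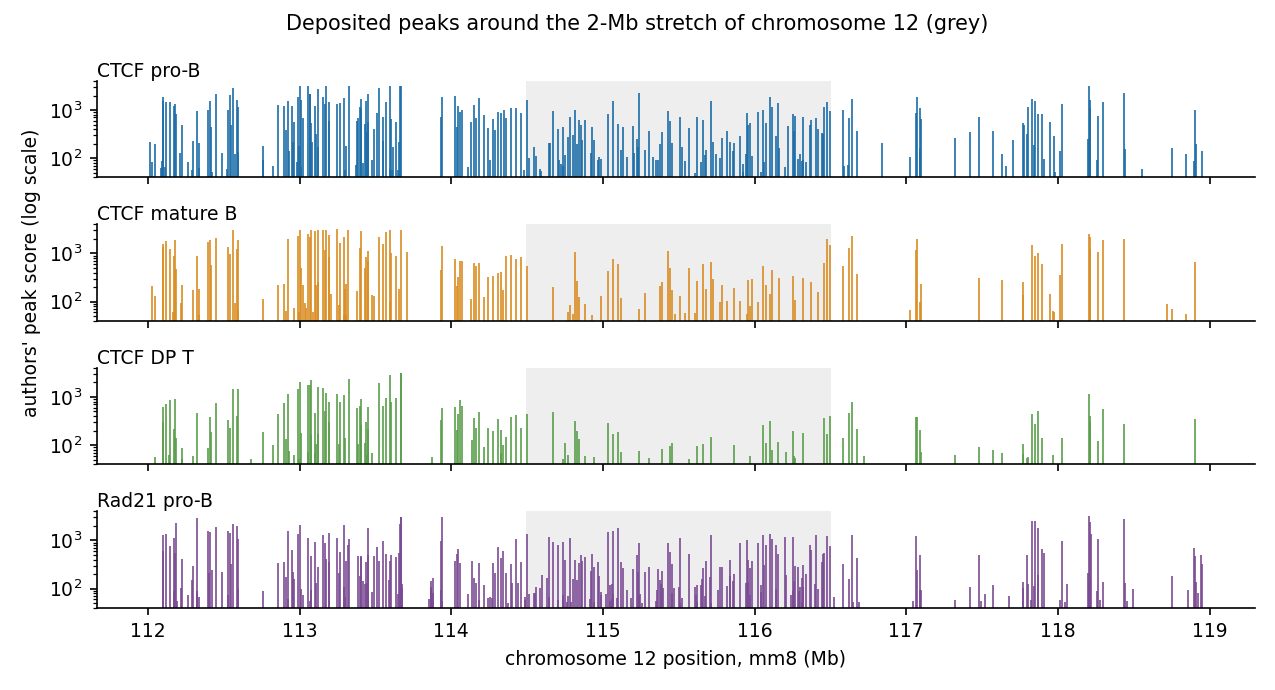
Each vertical line is a deposited peak on chromosome 12 (mm8 position in Mb, horizontal axis), and its height is the authors' score on a log axis, in 1 panel per library. Inside the grey 2-Mb stretch the CTCF panels hold 107, 54 and 37 peaks in pro-B, mature B and DP T cells and the Rad21 panel 141.

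Read coverage between sites was lower in wild-type than in pro-B cells over long parts of chromosomes 12, 6, 19, 14 and 5. In mature B cells the longest regions with at most 0.7 of the scaled pro-B coverage were 115250001 to 115800000 and 114700001 to 115200000 on chromosome 12. Their ratios were 0.511 (0.462 to 0.565) and 0.462 (0.414 to 0.514). In DP T cells the longest was 41000001 to 41500000 on chromosome 6, with a ratio of 0.424 (0.359 to 0.498), followed by 33050001 to 33500000 on chromosome 19 with 0.591 (0.524 to 0.665). Regions of 400 kb followed from 54350001 to 54750000 on chromosome 14, with 0.375 (0.316 to 0.443), and from 14900001 to 15300000 on chromosome 5, with 0.525 (0.460 to 0.597). The chromosome 5 region was also low in mature B cells and lies where the fourth column of the alignments differs in both pro-B libraries. Part of the chromosome 14 region, from 54350001 to 54600000, was low in mature B cells too, with a ratio of 0.627 (0.544 to 0.722). Relative to the typical density of each library, the chromosome 6 region stood at 0.426 in DP T cells, 0.808 in mature B cells and 1.00 in pro-B cells. The chromosome 14 region stood at 0.501, 0.878 and 1.33, the chromosome 19 region at 0.912, 1.22 and 1.54, and the chromosome 5 region at 0.920, 0.770 and 1.74, with 1.40 in the Rad21 library, so that there the pro-B density was above typical. The chromosome 12 region from 114700001 stood at 0.976 in DP T, 0.571 in mature B and 1.25 in pro-B cells, and that from 115250001 at 0.781, 0.630 and 1.24. The latter was thus low in both wild-type cell types. Set directly against DP T cells, mature B cells had a ratio of 0.543 (0.454 to 0.649) from 114700001 to 114950000 on chromosome 12. The longest region of that comparison, of 300 kb, was on chromosome 4 from 136300001 to 136600000 (0.638). Regions elsewhere on chromosome 12 and on chromosomes 1 and 11 shared the 250 kb of the one named. DP T cells set against mature B cells had 0.436 (0.354 to 0.529) from 41100001 to 41500000 on chromosome 6, which shared the greatest length of that comparison, 400 kb, with a region on chromosome 3 from 60150001 to 60550000 (0.597).

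Such regions were not rare, which limits the reading of long and shorter ones alike. There were 110 regions of at least 2 adjacent 50-kb bins in mature B cells and 428 in DP T cells, and in the opposite direction 150 and 362. In the Rad21 library, from the same cell type and genotype as the reference, there were 761 lower and 624 higher regions. The longest lower one was 19550001 to 20550000 on chromosome 7, with a ratio of 0.588. At 1000 kb it exceeded every region named above, so length alone does not set those apart.

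**Figure D4:**
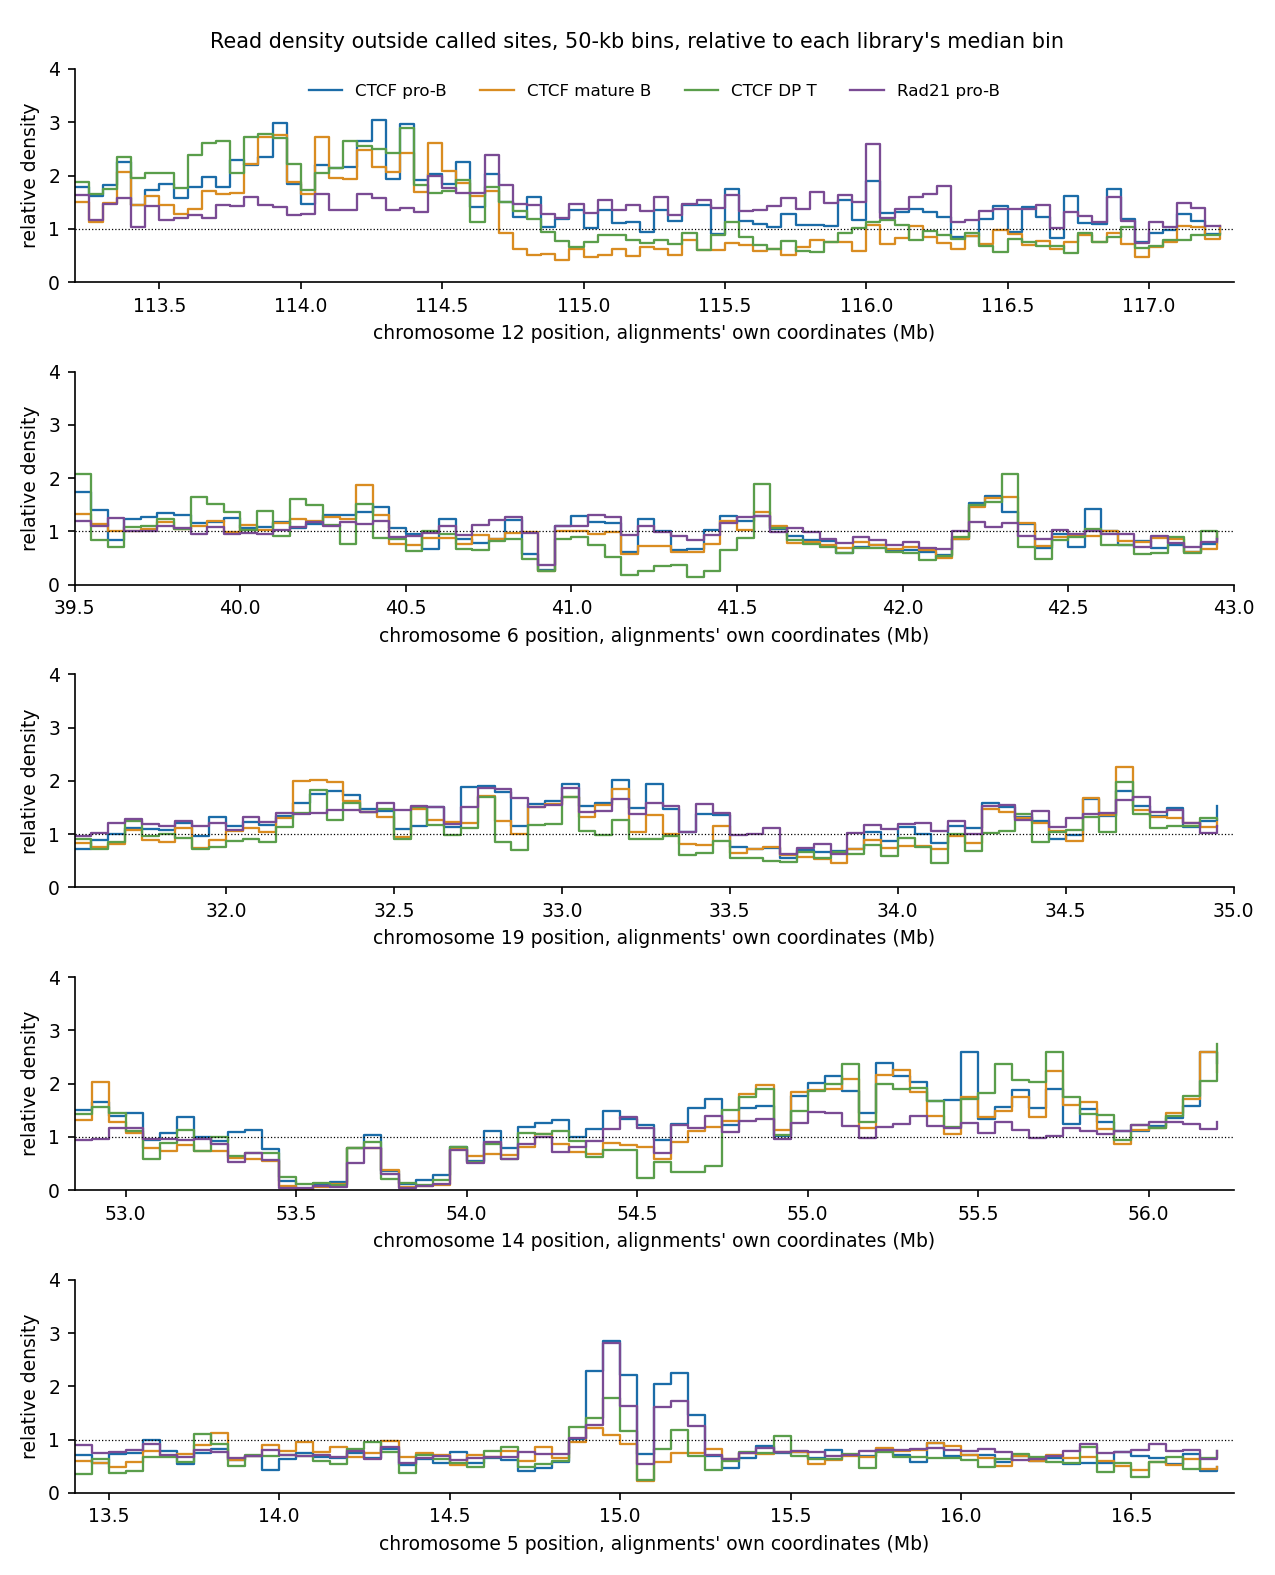
Read density outside called sites in 50-kb bins (vertical axis, relative to the median bin of each library) along parts of chromosomes 12, 6, 19, 14 and 5 (horizontal axis, the alignments' own coordinates in Mb), with 1 line per library. Mature B cells fall to 0.571 of their typical density from 114.7 Mb on chromosome 12, and DP T cells to 0.426 from 41 Mb on chromosome 6.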

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

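The tests of the Rag2 deletion and of strain segments were written before their outcomes were measured, while the minimum of 20 wild-type ends per stretch, the count of stretches on other chromosomes, the span of those on chromosome 2, the restriction of the deletion test to a single locus and the count of reads on chromosome Y were chosen after the data were seen.

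Part of chromosome 2 differed between the Rag2-/- and the wild-type libraries in a column of the alignments that no comparison of the report uses. In 17 bins of 1 Mb on chromosome 2, between 95000001 and 130000000, the share of distinct reads with a value above 0 in the fourth column was at least 5 points higher in both pro-B libraries than in both wild-type libraries, each taken relative to its own genome-wide median. The other 2 such bins among 2400 lay on chromosome 5, and no bin differed by 5 points in the opposite direction. The rise was greatest, at 23.9 points, from 122000001 to 123000000. Over the chromosome 2 span the median share was 26.8% in pro-B CTCF and 21.7% in Rad21, against 22.6% and 16.0% over the genome, whereas mature B had 19.8% against 20.5% and DP T 32.8% against 33.5%. The mouse RefSeq table puts Rag2 on chromosome 2.

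The Rag2-/- libraries also lacked reads over 67 stretches, on 15 chromosomes, where the wild-type libraries together held at least 20 ends, as on chromosome 7 from 27659251 to 27681500 and on chromosome 13 from 66013001 to 66073500. In the reverse direction 1533 stretches without wild-type ends were found, at a minimum scaled to the depth. The directions are not alike, since the pro-B pair held 1.83 ends per wild-type end and includes the Rad21 library. The counts therefore cannot tell whether such stretches are particular to the Rag2-/- libraries. A segment from another mouse strain, kept around the targeted gene, may carry deletions relative to the reference. Of the 67 stretches without pro-B ends 13.4% lay in bins with the rise in the fourth column. If that column counts mismatches, this is too many for the bound set against the explanation and too few for the majority it called for. The stretches are not independent, however. Chromosomes 13, 7 and 10 held 15, 11 and 8 of them, many close together, as on chromosome 13 between 65962251 and 66561000. The share thus depends on how such loci were split. The targeted deletion of Rag2 is excluded for the 56 stretches on other chromosomes than 2 and, as the 11 on chromosome 2 extend over 73.1 Mb, for these as a set, while for any single locus among them the deletion cannot be told apart from other sources, since chromosome 1 held 641 runs of 1-kb windows without pro-B ends and chromosome 2 held 642.

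Chromosome Y, which the site ratios and the coverage comparisons leave out, held 42 reads in CTCF pro-B, 3798 in mature B, 6772 in DP T and 12378 in Rad21 pro-B. The numbers of called sites per library and the shares of ends at CTCF sites did include both sex chromosomes. Chromosome X held 3.48%, 2.97%, 2.03% and 2.43% of the distinct ends. The 2 pro-B libraries thus differed from each other on both sex chromosomes. The labels give no sex, and no explanation was tested.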

How the results depend on the processing

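The equal-depth ratios, the restriction to sites called in the second library and the equal list lengths on chromosome 12 were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because each group has 1 library. Among the values that answer a comparison, 60 stayed within their counting interval, or within 1.5 times for a count, and 92 moved further. Each of these is a single count or percentage, so a change of direction was not scored for them. The split between mature B and DP T cells turned among sites called in DP T cells. That restriction favours DP T cells by construction. The shares of pro-B peaks in mature B cells and of mature B peaks in pro-B cells also changed order. They were 65.6% and 90.3%, and 83.7% and 82.9% with equal list lengths. Unless the construction of a setting shows it, the cause was not tested. Counting reads over receptor loci with all reads was not run, since the loci were not placed.

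Windows called at equal depth numbered 28271 in pro-B, 20885 in mature B and 17522 in DP T cells, below the authors' lists, which rest on more reads for pro-B and mature B and on another caller.

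Percentages of shared peaks are given in a fixed order: pro-B in mature B, pro-B in DP T, mature B in pro-B, mature B in DP T, DP T in pro-B, DP T in mature B. With scores of at least 100 they were 68.6, 50.9, 93.4, 66.8, 96.9 and 93.6, and with peak centres within 200 bp 41.7, 31.3, 58.0, 40.3, 53.5 and 49.5. With a reciprocal overlap of 50% they were 60.1, 45.5, 83.6, 59.2, 77.9 and 72.8, and with equal list lengths 83.7, 77.6, 82.9, 78.3, 79.0 and 80.6. Pro-B peaks in both other lists came to 20.3% by centres, 40.2% by reciprocal overlap and 72.8% with equal lengths. Without chromosomes X and Y, 52.1% of pro-B peaks were in DP T cells. The lower values by centres and reciprocal overlap follow from stricter definitions.

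Pro-B CTCF peaks with Rad21 came to 50.0% by centres (49.98), 31.9% by reciprocal overlap and 74.3% with equal lengths. Rad21 peaks with pro-B CTCF came to 87.7% at scores of at least 100, 54.2% by centres, 34.6% by reciprocal overlap and 78.9% with equal lengths, and Rad21 peaks with any CTCF list to 89.4%, 69.3%, 52.8% and 81.5%.

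Counts of sites at least 2-fold higher and lower in the first cell type depended on the count minimum by construction. For pro-B against DP T they were 15758 and 784 with at least 20 ends, 2930 and 228 with at least 100, and 14515 and 1171 with all reads. Scaling by total reads left 254 lower, equal depth gave 847 lower, and sites called in DP T cells, with counts at equal depth, gave 806 and 796. For pro-B against mature B they were 13904 and 710, 2224 and 140, and 12617 and 950, and sites called in mature B cells gave 2893 higher. For mature B against DP T they were 6368 and 1783, 1729 and 145, and 5946 and 2737. Equal depth, with its lower minimum of ends, gave 1640 lower. Sites called in DP T cells, counted the same way, gave 726 higher and 1442 lower, the opposite of the split over sites called in any library.

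Of 720 values for the 72 named sites under 10 settings, 717 stayed in their interval and none turned. The 3 others were the chromosome 2 site at 120304201 with all reads, at a log2 ratio of -1.35 to DP T and -1.69 to mature B cells, and the chromosome 10 site at 120857001 with background subtracted, which fell below its interval. This is a weak check. The 12 sites with the highest ratio of each pair had 0 ends in the other library, so their intervals have no upper limit. The count minimums leave the ratio of a site unchanged.

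The median Rad21 fold over the genome mean at sites of all 3 cell types was 18.7 with all reads and 30.7 in windows of 150 bp each side. It was 4.61 and 7.50 at pro-B-only sites, and in the narrow windows 4.65 at mature B-only and 2.86 at DP T-only sites. Shared sites matched on CTCF count had 5.36, 8.58 and 13.2 beside the pro-B-only, mature B-only and DP T-only classes, the latter pair matched on mature B and DP T counts and so unequal in pro-B CTCF. In the chromosome 12 stretch, equal list lengths gave 61 pro-B and 82 Rad21 peaks, and scores of at least 100 gave 21 DP T peaks.

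Regions of lower coverage numbered 23 in mature B, 86 in DP T and 337 in Rad21 with 100-kb bins, and 840, 1558 and 1667 with a ratio of at most 0.8, by construction. Reads in peaks counted too gave 285 in mature B and 1725 in Rad21, all reads 213 in mature B and 827 in DP T, and Rad21 as the reference 328 and 1372. Of 168 values for the 36 named regions 130 stayed in their interval, 37 moved, and 1 passed 1: mature B cells on chromosome 11 from 80050001 had a ratio of 1.15 to Rad21.

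Depth limits the DP T library most, with 6543135 distinct ends. In the simulation 33.7% of the weaker sites were called at that depth, against 83.8% at the pro-B depth.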

Other observations

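The tests of coverage and of site ratios in this part were all chosen after the results were seen.

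Chromosome 12 also held gains in DP T cells, in peaks and in coverage. The coordinates of peaks and coverage were not joined, so whether these gains coincide is not known. Among 4931 windows of 500 kb, that from 108000001 to 108500000 (mm8) had the largest excess of DP T over pro-B peaks, with 14 CTCF peaks in DP T, 4 in pro-B and 3 in mature B cells. On the alignments' own coordinates, the 3 longest regions of higher DP T coverage between sites were on chromosome 12, from 107450001 to 107850000 with a ratio of 1.71 to pro-B, from 108950001 to 109300000 with 1.92 and from 108250001 to 108600000 with 1.73. The window with the largest excess of pro-B over DP T peaks was on chromosome 18 from 37500001 to 38000000 (mm8), with 41 peaks in pro-B, 22 in mature B and 10 in DP T cells and 28 Rad21 peaks. These windows and regions were chosen after their values were seen.

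Long regions of lower coverage than in pro-B cells numbered 6 in the wild-type libraries at a length of at least 400 kb. Of these, 4 were on the chromosomes of Igh, Tcrb and Tcra. On chromosomes 19 and 5 the DP T density was 0.912 and 0.920 of typical and the pro-B density 1.54 and 1.74. DP T cells were thus low there mainly relative to pro-B cells. A peculiarity of the single pro-B CTCF library is argued against, since the ratio to the Rad21 pro-B library was at most 0.640 in each of the 6 regions. The meaning of the fourth column is not given in the sources used here. If it counts mismatches, the region on chromosome 5 may be a strain segment of the Rag2-/- mice. The column rose there by 12.1 points in the pro-B libraries. In the 5 regions on other chromosomes the rise was at most -0.25 points, which on the same condition argues against that source there. For the 4 regions on receptor chromosomes, loss of DNA by rearrangement in the wild-type cells could lower the coverage, and the density of the affected library was at most 0.630 of its typical value, but without locus positions on this assembly it cannot be told apart from other differences between the cells.

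More sites were 2-fold higher than lower in pro-B cells. Against mature B cells, deeper sequencing is argued against as the whole cause, since the pro-B library held 0.980 distinct ends for each distinct end of the mature B library. The choice of sites is argued against too, with 83.2% among the sites called from the unthinned mature B reads and counted at equal depth. This restriction works against the excess. Against DP T cells, with counts at equal depth, the share was 50.3% among the sites called in DP T and 93.6% among those called in pro-B cells. The calls came from the unthinned reads, and each restriction favours the library that called. The choice of sites thus cannot be told apart from an excess at the sites themselves. Cell stage, the Rag2 genotype and the quality of the single libraries stay open for the excess over mature B cells, as the design does not separate them.

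In each of the 4 libraries 1 stretch of 10 kb, on chromosome 2 from 98500001 to 98510000, took the most reads: 0.752% in pro-B, 0.781% in mature B, 2.00% in DP T and 1.36% in Rad21.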
